A study of Mus musculus with 8 samples.

How the data were processed

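Bone marrow-derived macrophages came from female Fvb mice aged 6 to 8 weeks, per the labels. They were left untreated or stimulated with lipopolysaccharide and interferon gamma, and chromatin was immunoprecipitated from 500000000 cells for Jmjd3 and 100000000 per time point for the other antibodies, per the labels' protocols. Fragments of about 200 to 300 bp were sequenced, and over 10000000 uniquely mapped tags were obtained per library, per the labels. Libraries were grouped by antibody and time from their labels, with 1 library in each of the 8 groups.

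The deposited files are peak lists, 1 per library, whose only value is a whole-number overlap count at each peak, a signal that the authors gave without scaling to depth or to a control as far as the headers and labels say. Per the file headers, Jmjd3, H3K27me3 and Pol II peaks are single positions, and H3K4me3 peaks are clusters with a start and an end. Coordinates are on mm8 per the submitters' processing notes. The aligner, peak caller, threshold and control library are not given in the sources used here. The lowest count was 9 for Jmjd3, H3K27me3 at 0 h and Pol II at 0 h, 10 for H3K27me3 at 4 h and Pol II at 2 h, and 11 for both H3K4me3 lists and Pol II at 4 h, so the lists did not share 1 lowest count. Exact depth per library was unknown; a deeper library can list more low peaks, and heights were used to rank or class peaks within their own list, except in 1 alternative that set the lowest count of one list as a floor for another and so put heights of libraries of unknown depth on 1 scale.

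Each single position was given a window of 500 bp (250 bp to each side), so that positions less than 500 bp apart overlapped, and peaks sharing at least 1 bp counted as overlapping. The window was not in the plan made before the data were examined; it was needed because the positions have no width. Positions within a list were over 500 bp apart. Shares are given with exact Clopper-Pearson intervals at 95% and differences of shares with 95% Wald intervals. Random placements (1000, seed 20) moved each peak on its own chromosome within the span covered by the 8 lists, or within 100 kb of its position. They were uniform and not limited to sequence where tags map uniquely. Height classes were bounded by a list's quartiles, with equal counts kept in 1 class. An earlier form that split equal counts by chromosome order was corrected after the first values had been seen. For matching, the comparison peaks were weighted to the height classes of the peaks of interest. Classes were the 4 of the list unless stated; for clusters with both marks, H3K4me3 height alone was matched in 10 classes, H3K27me3 height in 4, and both in 4 by 4 and then 10 by 4.

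A peak was called gained or lost when the list of the other time had no overlapping peak; this describes 2 lists and is not a test between conditions. Named regions followed a rule set before the data were examined: the 10 tallest Jmjd3 peaks, and the 5 tallest gained and lost peaks of Pol II, H3K4me3 and H3K27me3, and the 5 widest H3K27me3 peaks of each time. The H3K27me3 peaks have no width, so the widest were taken after merging peaks under 1 kb apart. Where fewer than 5 are printed, they are from the top of the order.

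Planned lists of genes were not run. The gene table at hand is on GRCm38.p6, another build than mm8, and its coordinates were not used, so regions are named by position and gene annotation is not analysed here.

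Alternatives set before the data were examined were an overlap of at least 50% of the shorter peak, positions within 1 kb counted as shared, peaks above the median height of each list, lists of equal length, merged peaks, autosomes alone, placement within 100 kb, distances of 1 and 20 kb to Jmjd3 and, for H3K27me3, covered length in place of peaks. Removing Jmjd3 peaks that overlap all 7 other lists, matching for height in 4 classes and then in 20, counting only peaks at or above the other list's lowest count, leaving out chromosome ends, covered length for Pol II and H3K4me3 and the gain of H3K27me3 near Jmjd3 at matched height were added after seeing the data. A list was taken to stop early on a chromosome when its last peak lay over 1 Mb before the last peak of every other list of that antibody. This was so only for Pol II at 0 h, on 7 chromosomes, and all lists were then cut at that position.

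Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlap counting was tested on simulated lists, where 1234 of 1234 planted overlaps among 4000 peaks were recovered, and 10 overlaps between the real lists were checked against bedtools 2.31.1, with identical counts.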

Results

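Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recorded where a protein or histone mark sat along the genome of mouse bone marrow-derived macrophages, the phagocytes grown in culture from marrow precursors. The antibodies were against Jmjd3, an enzyme that removes methyl groups from lysine 27 of histone H3; H3K27me3, the Polycomb mark that Jmjd3 acts on; H3K4me3, a mark of promoters; and RNA polymerase II (Pol II). Cells were left untreated (0 h) or were given lipopolysaccharide and interferon gamma, a bacterial cell wall component and a cytokine that together set off an inflammatory response. Jmjd3 was mapped at 2 h, H3K4me3 and H3K27me3 at 0 and 4 h, and Pol II at 0, 2 and 4 h. Each of the 8 combinations of antibody and time was 1 library, so no difference between times had a replicate check and no p-value was computed. Intervals in brackets are exact 95% binomial intervals unless named otherwise; they cover counting error only, since neighbouring peaks are not independent.

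The Jmjd3 list held 4398 peaks. H3K4me3 clusters numbered 21418 at 0 h and 19631 at 4 h, with median widths of 2808 and 2870 bp. H3K27me3 peaks numbered 59684 at 0 h and 89093 at 4 h, and Pol II peaks 55600 at 0 h, 57200 at 2 h and 57513 at 4 h. The overlap count that the authors gave each peak, called its height here, had a median of 10 for Jmjd3, 78 and 97 for H3K4me3 at 0 and 4 h, 12 and 13 for H3K27me3, and 14, 17 and 19 for Pol II at 0, 2 and 4 h. Each library had over 10000000 uniquely mapped tags per the labels, and the exact depth of each was unknown. List lengths and heights are therefore set side by side as values. The Pol II list of untreated cells stopped 3.04 to 17.3 Mb before the 2 and 4 h lists on chromosomes 13 to 18 and X; these 7 chromosome ends held no listed Pol II peak at 0 h, against 1216 at 2 h and 1466 at 4 h, and 114 Jmjd3 peaks. A Pol II peak there counts as absent at 0 h whatever untreated cells held.

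The first comparison asked which chromatin Jmjd3 occupied in stimulated cells. Jmjd3 peaks lay mostly in H3K4me3 clusters and at Pol II peaks, and seldom at H3K27me3 peaks. Of the 4398 Jmjd3 peaks, 83.3% (82.1 to 84.4) overlapped an H3K4me3 cluster of untreated cells and 84.0% (82.9 to 85.1) one of cells at 4 h. Pol II overlapped 67.0% (65.5 to 68.4) at 0 h, 80.7% (79.5 to 81.9) at 2 h and 78.6% (77.4 to 79.9) at 4 h. H3K27me3 overlapped 12.0% (11.02 to 13.0) at 0 h and 11.03% (10.1 to 12.0) at 4 h.

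In 1000 random placements of the Jmjd3 peaks on their own chromosomes, the mean overlap was 3.42% for H3K4me3 at 0 h, 2.43% for Pol II at 2 h and 2.51% for H3K27me3 at 0 h. The observed overlaps were 24.3, 33.2 and 4.77 times those means. Placements were not limited to sequence where tags map uniquely, which can lower their means and raise these factors. Placements within 100 kb of each peak, which keep the local density of marks, had higher means, and the observed overlaps were then 6.99 times the mean for H3K4me3 at 0 h, 6.42 times for Pol II at 2 h and 2.48 times for H3K27me3 at 0 h. For H3K27me3 at 4 h the factor was 3.02 over the chromosome and 1.79 within 100 kb. The observed number was above the highest of the 1000 placements for each of the 7 lists in both schemes. Part of the H3K27me3 overlap came from 198 Jmjd3 peaks that overlapped all 7 lists. Without them it was 7.81% at 0 h and 6.83% at 4 h, lower by definition. Placements of all Jmjd3 peaks within 100 kb reached at most 5.82% at 0 h and 7.30% at 4 h. Their mean was 6.16% at 4 h. Placements were not rerun without those peaks, so the excess within 100 kb at 4 h may rest on them.

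**Figure D1:**
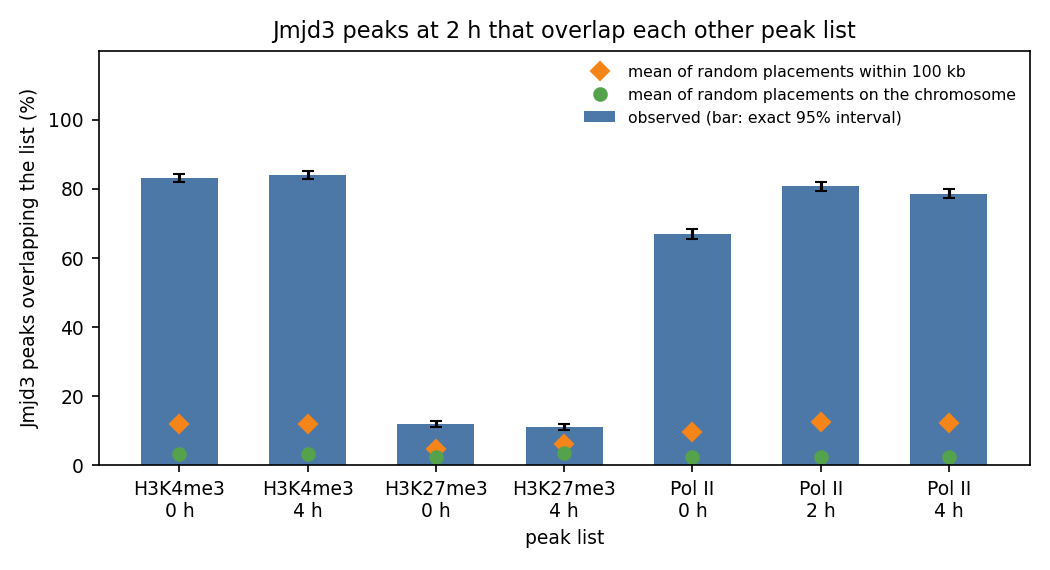
Share of the 4398 Jmjd3 peaks (vertical axis, percent) that overlapped each of the 7 other peak lists (horizontal axis). Blue bars are observed shares with exact 95% intervals, green circles and orange diamonds are means of 1000 random placements on the chromosome and within 100 kb; the bars stand at 67.0 to 84.0% for H3K4me3 and Pol II and at 11.03 to 12.0% for H3K27me3.

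By combined state, with all times of a mark pooled, 3030 Jmjd3 peaks (68.9%, 67.5 to 70.3) had H3K4me3 and Pol II without H3K27me3. A further 471 (10.7%, 9.81 to 11.7) had all of H3K4me3, Pol II and H3K27me3. Pol II alone accompanied 273 peaks, H3K4me3 alone 223 and H3K27me3 alone 44, and 266 peaks (6.05%, 5.36 to 6.79) overlapped none of the 7 lists. Across time, 760 Jmjd3 peaks (17.3%, 16.2 to 18.4) had a Pol II peak at 2 h and none at 0 h, against 154 (3.50%, 2.98 to 4.09) with the reverse. Without the 7 chromosome ends, 663 of 4284 (15.5%, 14.4 to 16.6) had Pol II at 2 h and none at 0 h, and 68.7% (67.3 to 70.1) overlapped Pol II at 0 h. H3K27me3 was listed at both times at 405 Jmjd3 peaks, at 0 h and not 4 h at 121, and at 4 h and not 0 h at 80.

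Taller Jmjd3 peaks overlapped H3K4me3 and Pol II more often. Among the 1426 peaks at the lowest height of 9, 71.9% (69.5 to 74.3) overlapped H3K4me3 at 4 h and 71.2% (68.8 to 73.6) Pol II at 2 h. Among the 970 peaks of height 14 to 96 these shares were 96.3% (94.9 to 97.4) and 90.5% (88.5 to 92.3). H3K27me3 at 0 h overlapped 7.78% (6.45 to 9.30) of the lowest peaks and 23.3% (20.7 to 26.1) of the highest, and peaks overlapping none of the 7 lists went from 12.1% (10.4 to 13.9) to 1.03% (0.495 to 1.89). Peaks overlapping all 7 lists, which overlap H3K27me3 by definition, were part of the H3K27me3 rise. They were 28 of the 111 lowest peaks at H3K27me3 at 0 h and 121 of the 226 highest.

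**Figure D2:**
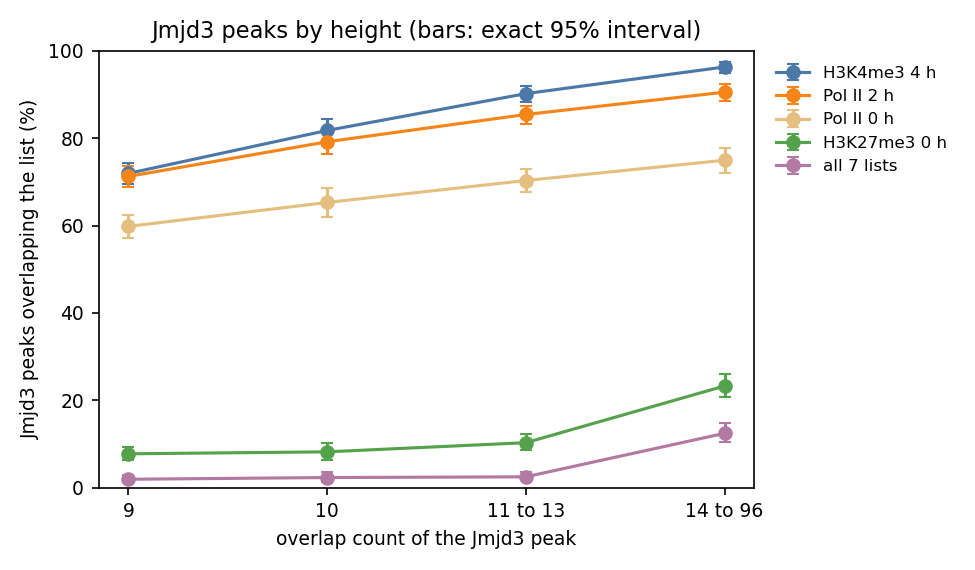
Share of Jmjd3 peaks overlapping a list (vertical axis, percent) in 4 classes of Jmjd3 overlap count (horizontal axis), with exact 95% intervals. All lines are higher in the tallest class than in the lowest, from 71.9 to 96.3% for H3K4me3 at 4 h and from 1.96 to 12.5% for peaks overlapping all 7 lists.

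The tallest Jmjd3 peak (height 96) was at position 146565410 on chromosome 5 (mm8, as are all coordinates), followed by position 69864537 on chromosome 4 (85) and position 3093181 on chromosome 11 (71). All 10 of the tallest overlapped H3K4me3 at both times and Pol II at 2 and 4 h. H3K27me3 overlapped 9 of the 10 at 0 h and 9 at 4 h, the exception at both times being position 3151521 on chromosome 6, and Pol II at 0 h overlapped 9, the exception being position 165333500 on chromosome X, 10.5 Mb beyond the last 0 h Pol II peak of that chromosome. Over the whole list, 198 Jmjd3 peaks (4.50%, 3.91 to 5.16) overlapped all 7 other lists. Without them the overlap with H3K27me3 was 7.81% (7.02 to 8.66) at 0 h and 6.83% (6.09 to 7.64) at 4 h. It is lower by definition, since each removed peak overlapped H3K27me3 at both times.

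The next comparison asked where Pol II was listed before and after stimulation. At 2 h, 28366 of the 57200 Pol II peaks (49.6%, 49.2 to 50) had no overlapping peak at 0 h and are called gained, and 26773 of the 55600 peaks at 0 h (48.2%, 47.7 to 48.6) had none at 2 h and are called lost. At 4 h, 26018 peaks (45.2%, 44.8 to 45.6) were gained and 24103 (43.4%, 42.9 to 43.8) lost against 0 h. The 2 and 4 h lists were closer to each other, with 32.3% (31.9 to 32.7) of the 4 h peaks absent at 2 h and 32.0% (31.6 to 32.4) of the 2 h peaks absent at 4 h; with positions within 1 kb counted as shared, these were 17.3% and 18.6%. Without the 7 chromosome ends, 48.5% (48.1 to 48.9) of the 2 h peaks and 43.8% (43.4 to 44.2) of the 4 h peaks were gained. Gained peaks were lower than kept peaks, with a median height of 14 against 28 at 2 h and 15 against 28 at 4 h.

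The tallest gained Pol II peaks at 2 h were at position 93423253 on chromosome 5 (height 397), position 10698566 on chromosome 16 (392), position 27041138 on chromosome 12 (390), position 83346578 on chromosome 11 (387) and position 93421337 on chromosome 5 (384). All 5 overlapped a Jmjd3 peak, an H3K4me3 cluster at 4 h and a Pol II peak at 4 h, and 3 overlapped H3K4me3 at 0 h. The chromosome 16 position was 501 bp from a Pol II peak of untreated cells, and the others were 1.16 to 21.1 kb from one. The tallest gained at 4 h were at positions 83346597, 83343728 and 83344371 on chromosome 11 (374, 362 and 328), position 97567627 on chromosome 16 (373) and position 78737090 on chromosome 11 (326), all 5 with Jmjd3. The 4 on chromosome 11 were 18.2 to 36.9 kb from a Pol II peak of untreated cells. The chromosome 16 position lay 9.94 Mb beyond the last 0 h Pol II peak of its chromosome, on 1 of the 7 chromosome ends. Positions 83346597, 83343728 and 83344371, and 83346578 at 2 h, lay at 1 locus, and the 2 chromosome 5 positions at 2 h were neighbours. The named peaks are therefore not all separate sites. Over all 4 h peaks of height 40 to 401, Jmjd3 was at 15.4% of gained and 20.6% of kept peaks. The 5 tallest lost at 4 h, led by position 81854480 on chromosome 11 (height 257), were each 586 to 786 bp from a Pol II peak at 4 h.

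Overlapping Pol II peaks of the 3 times formed 93719 regions. Regions listed at all 3 times numbered 24651, and 11.4% (11.04 to 11.8) of them held a Jmjd3 peak. Regions listed at 2 and 4 h and not at 0 h numbered 13715, with Jmjd3 at 4.14% (3.81 to 4.49), and 12850 with 3.72% (3.40 to 4.06) without the 7 chromosome ends. Jmjd3 was at 1.26% (1.08 to 1.46) of the 13909 regions listed at 2 h only, 0.807% (0.651 to 0.987) of the 11531 listed at 4 h only and 0.386% (0.304 to 0.483) of the 19696 listed at 0 h only.

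**Figure D3:**
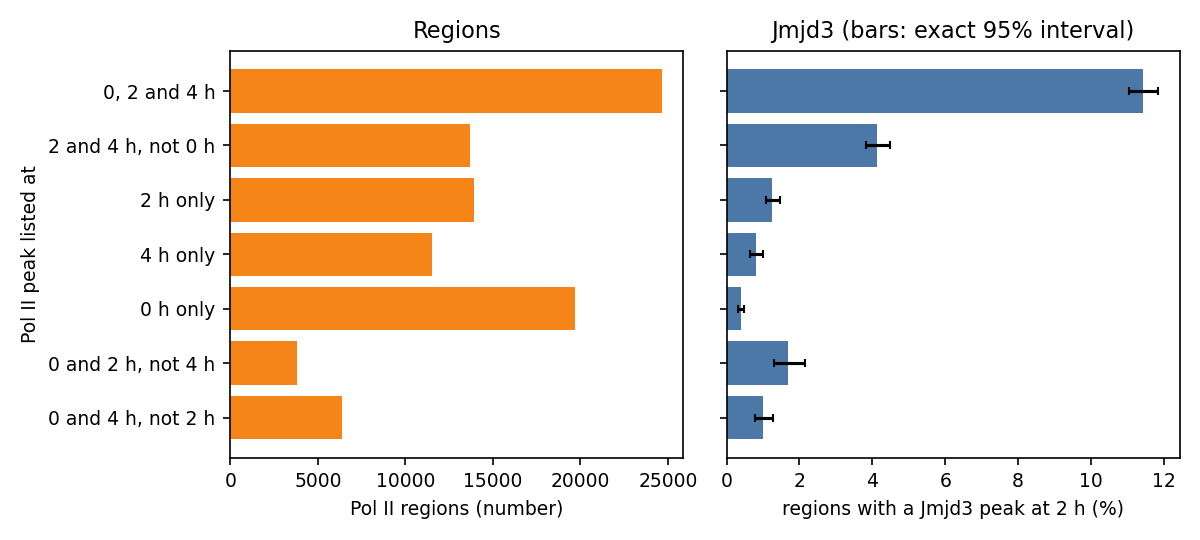
Number of Pol II regions (left, horizontal axis) and share holding a Jmjd3 peak (right, horizontal axis, percent, with exact 95% intervals) by the times at which Pol II was listed (vertical axis). The share with Jmjd3 was 11.4% where Pol II was listed at all 3 times, 4.14% at 2 and 4 h only and 0.386% at 0 h only.

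Jmjd3 was less frequent at gained than at kept Pol II peaks. At 2 h, 2.64% (2.45 to 2.83) of gained and 9.81% (9.47 to 10.2) of kept peaks overlapped Jmjd3, a difference of -7.17 percentage points (95% Wald interval -7.57 to -6.78), and at 4 h the difference was -6.39 points (-6.76 to -6.02). With kept peaks weighted to the heights of the gained ones in 4 classes, the differences were -0.362 (-0.609 to -0.114) and -0.597 points (-0.849 to -0.345), and in 20 classes they were 0.224 (-0.0194 to 0.466) and -0.105 points (-0.352 to 0.143). In the tallest class at 2 h, heights 39 to 402, Jmjd3 was at 18.0% (16.5 to 19.6) of 2343 gained and 21.7% (20.9 to 22.5) of 11663 kept peaks. Lost peaks held Jmjd3 less often than kept ones in the tallest class too: of the 0 h peaks of height 25 to 351, 3.30% (2.54 to 4.22) of 1847 lost by 2 h and 18.6% (17.9 to 19.3) of 11667 kept overlapped Jmjd3.

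H3K4me3 clusters were compared between 0 and 4 h in the same way, with widths of about 2.8 kb against the 500 bp windows of the other marks. Of the 19631 clusters at 4 h, 995 (5.07%, 4.77 to 5.38) were gained, and of the 21418 at 0 h, 2810 (13.1%, 12.7 to 13.6) were lost. Gained clusters were low, with a median height of 12 against 109 for kept ones, and lost clusters had a median of 13 against 111. With both lists cut at their own median heights, 0.757% were gained and 9.22% lost. Those shares also count clusters whose partner lay at or below the other list's median. In the full lists, 3 of the 0 h clusters of height 79 to 182 and 0 of the taller ones were lost. At 4 h, 5 clusters of height 98 to 193 and 0 of the taller ones were gained. In lists of equal length, which bring the shares together by construction, 7.73% were gained and 8.16% lost. By covered length, 14.7% of the 4 h clusters' length was gained and 19.98% of the 0 h length lost. With positions within 1 kb counted as shared, 12.5% of H3K4me3 clusters and 12.9% of H3K27me3 peaks were lost.

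The tallest gained H3K4me3 cluster (height 134) spanned 83341376 to 83346967 on chromosome 11. It was followed by 105530499 to 105534857 on chromosome 5 (111), 60337237 to 60342378 on chromosome 18 (105), 34464918 to 34472188 on chromosome 17 (101) and 105374881 to 105381009 on chromosome 5 (101). All 5 held Jmjd3 and Pol II at 2 and 4 h, and 1, the chromosome 17 cluster, held Pol II at 0 h. That cluster also overlapped H3K27me3 at 0 h and not at 4 h; the other four overlapped no H3K27me3 peak. Within 4 kb of the chromosome 11 cluster, 6 Jmjd3 peaks, 9 Pol II peaks at 2 h and 11 at 4 h were listed, and none of Pol II at 0 h or of H3K27me3. An H3K4me3 cluster of untreated cells (height 21) lay 3.32 kb from the chromosome 11 cluster. The chromosome 17 cluster was 4.885 kb from one, and the others were 23.3 to 264 kb from one. The tallest lost cluster spanned 69829958 to 69832397 on chromosome 11 (height 139), and Jmjd3 overlapped 2 of the 5 tallest lost.

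**Figure D4:**
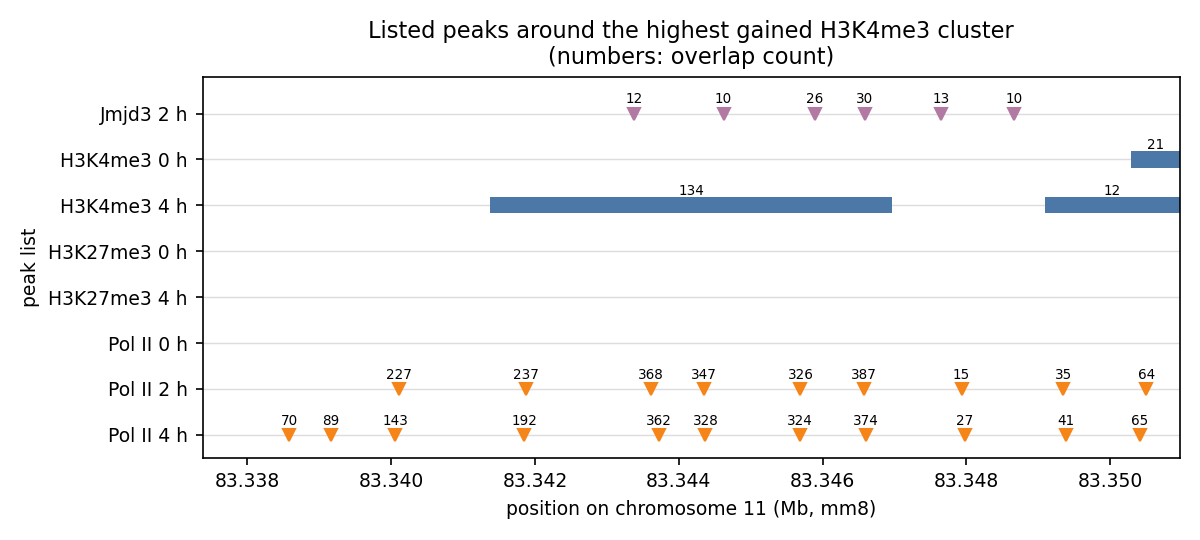
Peaks of the 8 lists (vertical axis) around the tallest gained H3K4me3 cluster, by position on chromosome 11 (horizontal axis, Mb). Triangles are single positions, bars are clusters (those at the right edge run on past the drawn window) and numbers are overlap counts; 6 Jmjd3 and 9 Pol II positions at 2 h stand where untreated cells had no Pol II peak.

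Jmjd3 overlapped 5.63% (4.28 to 7.25) of gained and 15.2% (14.7 to 15.7) of kept H3K4me3 clusters, a difference of -9.60 percentage points (Wald, -11.1 to -8.07). The direction turned at matched height: with kept clusters weighted to the heights of the gained, the difference was 2.19 points (0.657 to 3.72). Among clusters of height 11 to 23, which held 965 of the 995 gained, Jmjd3 was at 4.46% (3.24 to 5.96) of gained and 3.31% (2.78 to 3.91) of 4014 kept clusters. Among those of height 24 to 97 it was at 8 of 25 gained (32.0%, 14.9 to 53.5) and at 5.14% (4.53 to 5.80) of 4846 kept clusters.

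The comparison of H3K27me3 asked whether the mark was lost or gained where Jmjd3 bound. The H3K27me3 list was longer after stimulation. Of the 89093 peaks at 4 h, 46054 (51.7%, 51.4 to 52.0) were gained, and of the 59684 at 0 h, 16877 (28.3%, 27.9 to 28.6) were lost. That more were gained than lost follows largely from the unequal list lengths. With positions within 1 kb counted as shared, 33.1% were gained and 12.9% lost; in lists of equal length, where the shares are about equal by construction, both were 38.2%. By covered length, 63.1% was gained and 45.0% lost. The difference in H3K27me3 loss between peaks near Jmjd3 and elsewhere depended on the rule used. Of 1452 peaks within 5 kb of a Jmjd3 peak, 360 (24.8%, 22.6 to 27.1) were lost, against 28.4% (28.0 to 28.7) of the other 58232, a difference of -3.57 percentage points (Wald, -5.82 to -1.32). It was -7.15 (-9.57 to -4.74) in lists of equal length, -6.34 (-9.27 to -3.41) within 1 kb of Jmjd3 and -7.02 (-10.5 to -3.51) for direct overlap. The interval included 0 with positions within 1 kb counted as shared (-0.584, -2.30 to 1.13). It also did with all lists cut at their median heights (-2.68, -6.11 to 0.743). Without the Jmjd3 peaks overlapping all 7 lists it included 0 as well (-0.980, -3.51 to 1.55). Those peaks lie at H3K27me3 of both times by definition, so removing them favours a higher loss share near Jmjd3.

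Peaks near Jmjd3 were taller, with a median height of 14 against 11, and lower peaks were lost more often. Matched for height, the difference near Jmjd3 turned to 1.71 points, with an interval that includes 0 (-0.529 to 3.96). By height class, 50% (44.7 to 55.3) near Jmjd3 against 45.0% (44.4 to 45.7) elsewhere were lost at heights 9 to 10, 36.7% (30.4 to 43.3) against 28.8% (28.0 to 29.6) at 11 to 12, 15.8% (12.0 to 20.2) against 16.8% (16.2 to 17.5) at 13 to 17, and 7.92% (5.77 to 10.6) against 9.42% (8.92 to 9.93) at 18 to 397.

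H3K27me3 peaks were also gained less often near Jmjd3: 34.9% (32.6 to 37.2) of the 1684 peaks at 4 h within 5 kb of Jmjd3 were absent at 0 h, against 52.0% (51.7 to 52.3) of the rest, a difference of -17.2 points (-19.5 to -14.9). Matched for height, it was -5.31 points (-7.61 to -3.02) in 4 classes and -4.79 (-7.08 to -2.50) in 20. This was not run without the Jmjd3 peaks overlapping all 7 lists. Those lie at H3K27me3 peaks of both times by definition, which favours a lower gained share near Jmjd3.

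**Figure D5:**
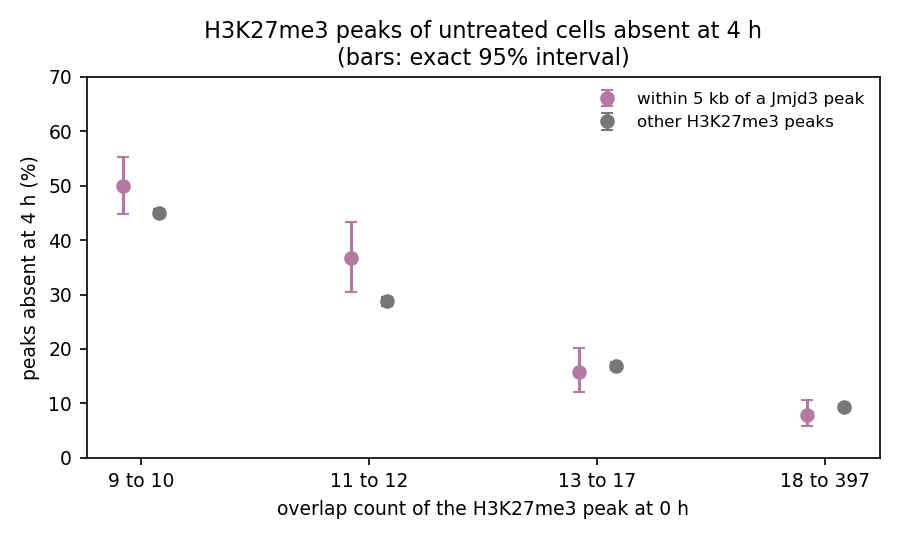
Share of H3K27me3 peaks of untreated cells with no peak at 4 h (vertical axis, percent) in 4 classes of overlap count (horizontal axis), for peaks within 5 kb of a Jmjd3 peak and for all others, with exact 95% intervals. The share falls from 50 to 7.92% near Jmjd3 and from 45.0 to 9.42% elsewhere.

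Most lost H3K27me3 peaks stayed close to the mark: 78.8% of them lay within 5 kb of a peak at 4 h, and 68.9% of gained peaks lay within 5 kb of a peak at 0 h. The tallest lost peak, position 4582853 on chromosome 17 (height 138), was 189 kb from the nearest peak at 4 h, and the next 4 were 518 to 786 bp from one. The 5 tallest gained peaks, led by position 39453347 on chromosome 17 (394), were 547 to 834 bp from a peak at 0 h. Jmjd3 overlapped none of these 10 peaks. The gained peak at 18209034 and the lost peak at 18209649 on chromosome 14 were 615 bp apart. The 10 are therefore not all separate sites. After merging peaks under 1 kb apart, the widest H3K27me3 domain spanned 75933898 to 75957120 on chromosome 15 at 0 h (23.2 kb) and 144028531 to 144057838 on chromosome 7 at 4 h (29.3 kb). All 10 of the widest domains overlapped H3K27me3 at both times and none overlapped Jmjd3.

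The last comparison asked how often H3K4me3 and H3K27me3 met. At 0 h, 5249 H3K4me3 clusters (24.5%, 23.9 to 25.1) overlapped an H3K27me3 peak, and at 4 h 5416 (27.6%, 26.96 to 28.2) did. These shares were 4.34 and 3.50 times the means of random placements on the chromosome, and 2.28 and 1.91 times those within 100 kb. Clusters with both marks were lower, with a median height of 50 at 0 h against 113 for H3K4me3 alone. They held Jmjd3 less often, at 8.88% (8.12 to 9.68) against 15.2% (14.6 to 15.8), a contrast not matched for height. Of the 0 h clusters kept at 4 h, Jmjd3 was at 3.54% of those of height 11 to 21. It was at 28.1% of those of height 183 to 361. Among clusters above the median height of their list, overlapping only H3K27me3 peaks above theirs, the shares were 11.9% at 0 h and 10.96% at 4 h.

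Of the 5249 clusters with both marks at 0 h, 4610 (87.8%, 86.9 to 88.7) kept both at 4 h and 367 (6.99%, 6.32 to 7.72) kept H3K4me3 with no H3K27me3 peak. Jmjd3 overlapped 23.2% of those 367 (85 clusters) and 8.16% of the 4610, a difference of 15.0 percentage points (Wald, 10.6 to 19.4). The clusters without H3K27me3 at 4 h had taller H3K4me3, with a median height of 156 against 51, and lower H3K27me3, with a median of 10 against 36. With kept clusters weighted to the same H3K4me3 heights in 10 classes, the difference was 2.51 points (-2.55 to 7.56), and to the same H3K27me3 heights in 4 classes 11.7 points (6.99 to 16.4). Weighted to both heights, it was 7.79 points (2.75 to 12.8) in 4 by 4 classes and 4.15 points (-1.53 to 9.82) in 10 by 4.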

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

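No test in this part was chosen after the result was seen. The numbers of listed peaks of the repressive mark and of the promoter mark moved in opposite directions after stimulation: the H3K27me3 list at 4 h held 29409 more peaks than at 0 h, while the number of H3K4me3 clusters fell by 1787. Each mark had 1 library per time, and the difference between these changes was not tested.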

How the results depend on the processing

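Matching for height in 4 and in 20 classes, removal of the Jmjd3 peaks overlapping all 7 other lists the floor set by the other list's lowest count, leaving out chromosome ends and covered length for Pol II and H3K4me3 were chosen after seeing the data; the other alternatives were set before. Of 215 alternative values for 40 results, 84 stayed within the 95% interval of the value reported (for list lengths, within 1.5 times of it), 125 moved outside it and 6 changed sign. The 6 were the Jmjd3 share at gained minus kept H3K4me3 clusters, matched for height in 4 and 20 classes and above the median heights, H3K27me3 loss near Jmjd3, matched in 4 and 20 classes, and the Jmjd3 share at gained minus kept Pol II peaks at 2 h, matched in 20 classes. The intervals of the matched H3K27me3 differences (-0.529 to 3.96 and -0.446 to 4.04) and of the Pol II one (-0.0194 to 0.466) include 0. The H3K4me3 value above the median heights counted a cluster as gained also when its 0 h partner lay at or below the 0 h median. No other difference between shares changed sign under the alternatives run. Intervals were narrow because the lists are long, so small shifts count as moved. Rules that count more or fewer positions as shared move the shares by construction. Equal lengths make gained and lost shares about equal by construction. Cutting both lists at their medians counts peaks with a lower partner as absent. Removing Jmjd3 peaks that overlap all 7 lists lowers the share of Jmjd3 peaks overlapping each list by definition. It also takes out Jmjd3 peaks at H3K27me3 of both times. For the other changes the cause was not tested. Depth per library was unknown, which limits every comparison of list lengths, and planned gene lists were not run. No paired analysis was possible because each antibody and time had 1 library. 

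With positions within 1 kb counted as shared, the share of Jmjd3 peaks overlapping a list was 84.6% for H3K4me3 at 0 h, 15.8% for H3K27me3 at 0 h and 15.2% for H3K27me3 at 4 h. It was 77.6% for Pol II at 0 h, 90.8% for Pol II at 2 h and 89.1% for Pol II at 4 h. The share of peaks with no partner at the other time was 36.8% for Pol II at 2 h absent at 0 h, 34.4% for Pol II at 0 h absent at 2 h, 31.5% for Pol II at 4 h absent at 0 h, 29.9% for Pol II at 0 h absent at 4 h and 17.3% for Pol II at 4 h absent at 2 h. It was 18.6% for Pol II at 2 h absent at 4 h, 4.72% for H3K4me3 at 4 h absent at 0 h, 12.5% for H3K4me3 at 0 h absent at 4 h, 33.1% for H3K27me3 at 4 h absent at 0 h and 12.9% for H3K27me3 at 0 h absent at 4 h. The Jmjd3 share at gained minus kept peaks was -7.72 points for Pol II at 2 h. H3K27me3 loss near Jmjd3 minus elsewhere was -0.584 points (-2.30 to 1.13). H3K4me3 clusters overlapped H3K27me3 in 25.9% at 0 h and 29.3% at 4 h. Above the median height of each list, the share of Jmjd3 peaks overlapping a list was 77.4% for H3K4me3 at 0 h, 78.8% for H3K4me3 at 4 h, 65.2% for Pol II at 0 h, 84.4% for Pol II at 2 h and 81.1% for Pol II at 4 h. Both lists were cut, so peaks whose partner lay at or below the other list's median counted as absent too. The share with no partner above that median was 46.5% for Pol II at 2 h absent at 0 h. It was 40.9% for Pol II at 0 h absent at 2 h and 42.8% for Pol II at 4 h absent at 0 h. It was 36.3% for Pol II at 0 h absent at 4 h and 26.4% for Pol II at 4 h absent at 2 h. This share was 25.6% for Pol II at 2 h absent at 4 h, 0.757% for H3K4me3 at 4 h absent at 0 h and 9.22% for H3K4me3 at 0 h absent at 4 h. It was 49.8% for H3K27me3 at 4 h absent at 0 h and 20.9% for H3K27me3 at 0 h absent at 4 h. In these cut lists the Jmjd3 share at gained minus kept peaks was -5.48 points for Pol II at 2 h and -4.96 points for Pol II at 4 h. It was 20.6 points for H3K4me3 at 4 h. In the full lists 5 clusters of height 98 to 193 and 0 of height 194 to 365 were gained. The 20.6 points therefore mostly counts as gained clusters that had a lower 0 h partner. H3K4me3 clusters overlapped H3K27me3 in 11.9% at 0 h and 10.96% at 4 h. In lists of equal length, the share of Jmjd3 peaks overlapping a list was 82.1% for H3K4me3 at 0 h and 9.50% for H3K27me3 at 4 h. The share of peaks with no partner at the other time was 48.9% for Pol II at 2 h absent at 0 h, 48.9% for Pol II at 0 h absent at 2 h, 44.4% for Pol II at 4 h absent at 0 h and 44.4% for Pol II at 0 h absent at 4 h. It was 7.73% for H3K4me3 at 4 h absent at 0 h, 8.16% for H3K4me3 at 0 h absent at 4 h, 38.2% for H3K27me3 at 4 h absent at 0 h and 38.2% for H3K27me3 at 0 h absent at 4 h. H3K27me3 loss near Jmjd3 minus elsewhere was -7.15 points (-9.57 to -4.74). H3K4me3 clusters overlapped H3K27me3 in 25.5% at 4 h. After merging peaks under 1 kb apart, the share of Jmjd3 peaks overlapping a list was 82.7% for H3K4me3 at 4 h, 71.4% for Pol II at 0 h, 84.0% for Pol II at 2 h and 82.2% for Pol II at 4 h. The share of peaks with no partner at the other time was 39.5% for Pol II at 2 h absent at 0 h, 39.7% for Pol II at 0 h absent at 2 h, 34.6% for Pol II at 4 h absent at 0 h and 37.0% for Pol II at 0 h absent at 4 h. It was 24.1% for Pol II at 4 h absent at 2 h, 26.5% for Pol II at 2 h absent at 4 h, 50.6% for H3K27me3 at 4 h absent at 0 h and 27.2% for H3K27me3 at 0 h absent at 4 h. The Jmjd3 share at gained minus kept peaks was -9.46 points for Pol II at 2 h and -8.85 points for Pol II at 4 h. The list held 37981 peaks for H3K27me3 at 0 h, 53428 peaks for H3K27me3 at 4 h, 34793 peaks for Pol II at 0 h, 34447 peaks for Pol II at 2 h and 33099 peaks for Pol II at 4 h. Under an overlap of at least 50% of the shorter peak, the share of Jmjd3 peaks overlapping a list was 8.96% for H3K27me3 at 0 h, 8.48% for H3K27me3 at 4 h, 53.96% for Pol II at 0 h, 66.8% for Pol II at 2 h and 65.4% for Pol II at 4 h. The share of peaks with no partner at the other time was 57.2% for Pol II at 2 h absent at 0 h, 55.9% for Pol II at 0 h absent at 2 h, 53.4% for Pol II at 4 h absent at 0 h and 51.8% for Pol II at 0 h absent at 4 h. It was 40.8% for Pol II at 4 h absent at 2 h, 40.5% for Pol II at 2 h absent at 4 h, 59.4% for H3K27me3 at 4 h absent at 0 h and 39.4% for H3K27me3 at 0 h absent at 4 h. The Jmjd3 share at gained minus kept peaks was -6.61 points for Pol II at 2 h and -5.91 points for Pol II at 4 h. Without the Jmjd3 peaks that overlap all 7 other lists, the share of Jmjd3 peaks overlapping a list was 7.81% for H3K27me3 at 0 h, 6.83% for H3K27me3 at 4 h and 65.4% for Pol II at 0 h. The Jmjd3 share at gained minus kept peaks was -6.50 points for Pol II at 2 h and -5.78 points for Pol II at 4 h. H3K27me3 loss near Jmjd3 minus elsewhere was -0.980 points (-3.51 to 1.55). Counting only peaks at or above the other list's lowest count, which compares heights between libraries of unknown depth, the share of peaks with no partner at the other time was 43.4% for Pol II at 0 h absent at 2 h, 33.2% for Pol II at 0 h absent at 4 h, 27.3% for Pol II at 2 h absent at 4 h and 22.2% for H3K27me3 at 0 h absent at 4 h. Without the 7 chromosome ends that the Pol II list at 0 h did not reach, 68.7% of Jmjd3 peaks overlapped Pol II at 0 h, and 48.5% of Pol II peaks at 2 h and 43.8% at 4 h were absent at 0 h. On the autosomes alone, the share of peaks with no partner at the other time was 50.6% for H3K27me3 at 4 h absent at 0 h and 27.8% for H3K27me3 at 0 h absent at 4 h. H3K4me3 clusters overlapped H3K27me3 in 23.5% at 0 h and 26.3% at 4 h. With heights matched in 4 classes, the Jmjd3 share at gained minus kept peaks was -0.362 points for Pol II at 2 h, -0.597 points for Pol II at 4 h and 2.19 points for H3K4me3 at 4 h. H3K27me3 loss near Jmjd3 minus elsewhere was 1.71 points. With heights matched in 20 classes, run after the values in 4 classes had been seen, the Jmjd3 share at gained minus kept peaks was 0.224 points for Pol II at 2 h, -0.105 points for Pol II at 4 h and 2.97 points for H3K4me3 at 4 h, and H3K27me3 loss near Jmjd3 minus elsewhere was 1.80 points. At a distance of 1 kb to Jmjd3, H3K27me3 loss near Jmjd3 minus elsewhere was -6.34 points. By covered length in place of peaks, the share of the length with no partner at the other time was 63.1% for H3K27me3 at 4 h absent at 0 h and 45.0% for H3K27me3 at 0 h absent at 4 h. It was 14.7% for H3K4me3 at 4 h absent at 0 h and 19.98% for H3K4me3 at 0 h absent at 4 h. For Pol II it was 60.5% at 2 h and 57.0% at 4 h absent at 0 h, 59.4% and 55.6% at 0 h absent at 2 and 4 h, 45.4% at 4 h absent at 2 h and 45.1% at 2 h absent at 4 h. With random placement within 100 kb, the observed overlap over the random mean was 6.99 for Jmjd3 with H3K4me3 at 0 h, 7.05 for Jmjd3 with H3K4me3 at 4 h, 2.48 for Jmjd3 with H3K27me3 at 0 h and 1.79 for Jmjd3 with H3K27me3 at 4 h. It was 7.02 for Jmjd3 with Pol II at 0 h, 6.42 for Jmjd3 with Pol II at 2 h, 6.41 for Jmjd3 with Pol II at 4 h, 2.28 for H3K4me3 with H3K27me3 at 0 h and 1.91 for H3K4me3 with H3K27me3 at 4 h.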

Other observations

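The tests of crowding within 10 kb and of Pol II height at 2 and 4 h were chosen after the results they bear on had been seen, as were the matchings in 20 height classes and in 10 by 4 classes, the group of 30 taller gained H3K4me3 clusters, the runs of Pol II peaks, the values without chromosome ends and the X chromosome values.

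Gained H3K4me3 clusters above the lowest height class of their list were few. Of the 30 clusters of height 24 to 134, 29 overlapped Pol II at 2 h, 27 at 4 h and 6 at 0 h, and 13 (43.3%, 25.5 to 62.6) held Jmjd3. Of the 965 gained clusters of height 11 to 23, 26.0% overlapped Pol II at 2 h and 4.46% (3.24 to 5.96) held Jmjd3. In the second height class, 24 to 97, Pol II overlapped 5 of 25 gained clusters at 0 h and 24 at 2 h, against 39.1% and 39.5% of kept clusters.

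Some long stretches of Pol II lay away from any listed Pol II peak of untreated cells, and part of them lay on the 7 chromosome ends that the 0 h list did not reach. Runs of at least 5 peaks, each over 5 kb from any 0 h peak, numbered 540 at 2 h and 465 at 4 h. The longest at 2 h covered 68725176 to 68910113 on chromosome 2 with 152 peaks and no Jmjd3, and the longest at 4 h covered 74219980 to 74421324 on chromosome 7 with 172 peaks and Jmjd3. Jmjd3 was in 17.2% (14.1 to 20.7) of these runs at 2 h and 18.9% (15.5 to 22.8) at 4 h. Runs formed from all peaks of a list that overlapped a 0 h peak held it in 46.0% (43.9 to 48.2) and 40.6% (38.5 to 42.7). The 2 sets could share peaks, and the first left out peaks near 0 h peaks by definition. Neither length nor height was matched, so the shares do not compare like with like. Without the 7 chromosome ends, 495 and 415 runs over 5 kb from any 0 h peak were left. They held Jmjd3 in 14.7% (11.7 to 18.2) and 16.1% (12.7 to 20.04).

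The X chromosome took a larger part of the H3K27me3 list after stimulation. Its peaks numbered 2527 at 0 h (4.23%, 4.07 to 4.40) and 5214 at 4 h (5.85%, 5.70 to 6.01), a factor of 2.06 against 1.47 on the autosomes. Of the X peaks at 4 h, 69.8% (68.6 to 71.1) were absent at 0 h, against 50.6% (50.2 to 50.9) on the autosomes, and the median height of the gained peaks was 11 on both.

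Jmjd3 peaks that overlapped all 7 other lists numbered 198. Of these, 61.1% (53.9 to 67.9) were above the upper quartile of Jmjd3 heights, against 970 of all 4398. On chromosome 11 before 3.2 Mb lay 43 of the 198 (21.7%, 16.2 to 28.1), against 72 of all 4398 (1.64%, 1.28 to 2.06). This stretch was not in the plan made before the data were examined. It takes in position 3093181, 1 of the 10 tallest Jmjd3 peaks, so its intervals describe a stretch not set beforehand. If a few crowded loci made up the set, most of its peaks would lie within 10 kb of another. The share that did was 31.3% (24.9 to 38.3), below 50%, though above the highest of 1000 random draws of as many Jmjd3 peaks (11.6%). A distance of 10 kb cannot show crowding over a longer stretch, such as that chromosome end. Sequence that collects tags in every library would place the Jmjd3 and H3K27me3 positions together, and the share within 50 bp was 10.3 percentage points (1.90 to 18.7) above that of the other Jmjd3 peaks overlapping H3K27me3 at 0 h, 39.9% against 29.6%. Heights were not matched: the median Jmjd3 height was 20 in the set and 11 at those other peaks. The difference therefore cannot be told apart from one of height. Such sequence may be part of the set and remains open, and no biological explanation was tested.

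Jmjd3 was less frequent at gained than at kept Pol II peaks, with differences of -7.17 and -6.39 percentage points at 2 and 4 h, and gained peaks were lower. Weighting kept peaks to the gained heights in 4 classes left differences of -0.362 (-0.609 to -0.114) and -0.597 points (-0.849 to -0.345), so a small remainder stayed. In 20 classes, run after those values had been seen, the differences were 0.224 (-0.0194 to 0.466) and -0.105 points (-0.352 to 0.143). The lower height of gained peaks may account for most of the gap, but since the reading of the remainder depended on the number of classes, it cannot be told apart from no difference. No biological explanation was tested.

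H3K4me3 clusters that had H3K27me3 at 0 h and none at 4 h held Jmjd3 more often than those that kept it, by 15.0 percentage points (10.6 to 19.4). Weighting to the same H3K4me3 height in 10 classes left 2.51 points (-2.55 to 7.56), and weighting to the same H3K27me3 height left 11.7 (6.99 to 16.4). Both heights in 4 by 4 classes left 7.79 points (2.75 to 12.8), and in 10 by 4 classes, run after that value had been seen, 4.15 (-1.53 to 9.82). Taller H3K4me3 may account for much of the difference, and whether a part remains that cannot be told apart from height depended on the classes used. Removal of the mark by Jmjd3 is a hypothesis that the design raises and that no test here decides, with 1 library per time; over all H3K27me3 peaks, loss near Jmjd3 at matched height differed from elsewhere by 1.71 points (-0.529 to 3.96).

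Pol II peaks on the mitochondrial chromosome numbered 12 at 0 h, 2 at 2 h and 4 at 4 h. The highest overlap counts lay between 351 and 402 in the 7 lists other than Jmjd3.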
